A study of Arabidopsis thaliana with 2 samples.

How the data were processed

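The samples were 2 libraries of anti-FLAG ChIP-seq, 1 from dark-grown and 1 from far-red-grown seedlings of the tagged FHY3 line. Per the labels' protocols, 5 g of 4-day-old seedlings were cross-linked with 1% formaldehyde, chromatin was sonicated and precipitated with a FLAG antibody, and Illumina libraries were made from the DNA. Per the submitters' processing notes the build was TAIR9, and the aligner is not given in the sources used here. The deposited files hold aligned reads, 1 line per read with start, end and strand, and all reads were 36 bp long. The deposited score column was 0 on every line and was not used. Positions repeated, so duplicates had not been removed. The read names place dark in lane 8 and far-red in lane 7 of a sequencing run. Groups follow the sample titles, and there was 1 library per group, so no p-value between conditions was computed.

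The strand column was read as reversed, a decision made after seeing the data. In chromosome arms, ends marked + lay to the right of ends marked − at a spacing with a maximum of 195 bp in dark (18.6 + ends per kb, against 5.88 at the same distance on the left, a 3.15-fold difference) and 215 bp in far-red (9.83 against 4.54, 2.16-fold). Read as labelled there was no such maximum. These spacings were used as fragment lengths, and each tag was moved by a fraction of that length to the fragment's middle.

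At most 1 tag per position and strand was kept, because nuclear reads per distinct tag averaged 6.60 in dark and 5.98 in far-red, and the dark library was thinned to 639237 tags. Tags were counted in 200 bp windows every 50 bp on the 5 nuclear chromosomes. Each window was set against the largest of the genome mean (1.07 tags per 200 bp) and the local means over 5000 and 10000 bp by a Poisson upper tail. Windows with a Benjamini-Hochberg q under 0.001 and at least 3-fold enrichment were merged within 200 bp, and the summit was the highest pileup. The q describes a window against its own library, not a condition. On simulated data for the dark library, with real tags moved at random by up to 5000 bp and 200 peaks planted, 46.3% of 67 peaks with 10 times the mean, 100% of 67 with 20 times and 100% of 66 with 40 times were found, with 0 false peaks over 2382907 windows. Of 100 planted peaks with 3-fold fewer far-red tags, the size rule found 6 of 33, 22 of 34 and 27 of 33 at these heights, and 1 of 100 equal peaks passed. The depth therefore limits what was found at low peaks. Moving the tags also spread out local clumps of the real background. The 0 false peaks therefore do not measure false calls in the real libraries.

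Peaks were called shared when summits lay within 200 bp, with exact binomial intervals, 1000 random moves within chromosomes and 20 random deals of the pooled tags. For the comparison of conditions, tags within 200 bp of each summit of the union were counted at equal depth, and a peak passed when the ratio was at least 2-fold and its exact conditional binomial interval was clear of 1. Shares of random tags used 2% of each library. Pericentromeres were the 44 of 240 bins of 500000 bp with protein-coding coverage under a fixed fraction of the median bin, 22 Mb in all.

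Gene names and neighbours came from an NCBI RefSeq gene table of the TAIR10.1 assembly, in which all 183 genes of the lists were matched. Its coordinates are not printed, since the build differs in name from that of the reads. A check of coordinate frames, by moving tags against genes in 49 segments of 2.5 Mb, found the best offset within 100 bp in 47. The table gives no strand, so promoter-bound was taken as a summit between 1000 bp outside either end of a protein-coding gene and 200 bp inside that end, in place of the planned side of the gene start. A reference sequence was not used here, so the share of peaks with the FHY3 binding site, the motif panel and lists matched on promoter GC content were not run. Peak positions are TAIR9, counted from 1.

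The 12 gene lists were fixed beforehand and cover light signalling, the clock, chlorophyll and haem biosynthesis, light harvesting, chloroplast division, abscisic acid, gibberellin, auxin, inositol and oxidative stress, published FHY3 targets, reference genes and seed storage genes. Each count was placed among 10000 random lists of the same size drawn from protein-coding nuclear genes, as a description of these libraries. Tags along gene bodies, added after seeing the data, were compared with 10000 lists matched on tags in 20 bins, on a log2 scale after adding 1. The named genes were fixed by rule. They are the 10 genes of highest enrichment in each library, the 5 peaks with the largest ratio in each direction among those that passed and lay near a gene, the bound members of each list (the 4 most enriched where more than 5 were bound) and FHY3 and FAR1. Members of the published list also bound under other lists are named there.

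Before the data were examined these alternatives were chosen: full depth, all reads kept, 2-fold and 5-fold minima, q under 1e-05, 400 bp windows, a genome-wide background, a strand filter, no pericentromeres, calls repeated in each of 2 random parts of a library, other gene and overlap distances, and other scalings. Added after seeing the data were the strand column as deposited, leaving out the FHY3 locus and the part of chromosome 2 from 3.2 to 3.6 Mb, a 100 bp minimum spacing of left and right tags, the ranking by fold over flanks, and summits anywhere in a list gene. Chloroplast and mitochondrial reads were left out of peak calling. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.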

Results

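FHY3 is a transposase-derived transcription factor of Arabidopsis that takes part in phytochrome A signalling, the pathway through which seedlings respond to far-red light. Its binding across the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 4-day-old seedlings of a line in which a FLAG- and HA-tagged FHY3, driven by the 35S promoter, was expressed in the fhy3-4 mutant. Seedlings were grown in darkness or in continuous far-red light, and the comparison asks where FHY3 sits on chromatin in each condition. There was 1 library per condition and neither an input nor a mock library was among the samples, so each library served as its own background and no difference between conditions has a replicate check. The dark library held 10186399 aligned reads of 36 bp, of which 5598661 lay on the nuclear chromosomes. The far-red library held 7866137 reads, 3819980 of them nuclear. Many reads repeated the same position and strand, and the nuclear reads came down to 848038 distinct tags in dark and 639237 in far-red. Both libraries were compared at 639237 distinct tags. All intervals are 95% intervals that cover counting error only, since reads without molecular identifiers are not independent molecules.

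FHY3 gave 1217 peaks in dark and 901 in far-red, with a median width of 350 bp in each. The 10 most enriched genes of each library made 17 different genes, of which 3 stood in both lists. All 17 had a peak called in both libraries, and 14 of the 17 summits lay outside the gene they were assigned to. In dark the list was led by AT2G24360 and AT2G01220, with 17.1-fold enrichment over the local background at each, followed by ARLA1C, which encodes an ARF-like GTPase, at 17.0-fold and AT1G07940 at 16.7-fold. RIF10, which encodes a chloroplast polynucleotide phosphorylase, stood at 16.5-fold, AT1G14570 at 16.1-fold, MIPS1 at 16.1-fold and AT3G58760 at 16.0-fold. LAX1, an auxin influx carrier gene, and NUDT21, a Nudix hydrolase gene, closed the list at 15.8-fold and 15.6-fold. The 10 far-red genes are given with their far-red values at the summits of the union of both libraries. They were AT1G14570 (15.7-fold), AT1G11970 (15.6-fold), EXPA9, an expansin gene (15-fold), AT5G40340 (14.9-fold) and AT2G01220 (14.9-fold). The others were AT4G33170 (14.8-fold), the D-type cyclin gene CYCD3;3 (14.7-fold), AT2G24360 (14.7-fold), AT1G50660 (14.6-fold) and AT3G04443 (14.6-fold). These values do not follow the far-red ranking exactly, since the highest enrichment at a called far-red summit was 15.59-fold. AT3G58760, listed for dark alone, had 15.53-fold in far-red at its union summit. The local background includes the tags of the peak itself, which limits enrichment to 25-fold. Ranking by fold over flanking sequence, a choice made after seeing the data, shared 3 of the 10 dark genes and 2 of the 10 far-red genes. Keeping all reads instead of 1 per position and strand gave 33760 dark and 37248 far-red peaks, which turned the order of the libraries.

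Most far-red peaks were also dark peaks. Of the 901 far-red summits, 727 lay within 200 bp of a dark summit, which is 80.7% (exact interval 78.0 to 83.2). Moving the peaks at random within chromosomes gave a mean of 0.408% and at most 1.44% over 1000 moves. When the tags of both libraries were pooled and dealt at random into 2 sets of equal size, 20 times, the shared share ran from 75.5% to 82.0%. The same matches made up 59.7% of the 1217 dark summits (56.9 to 62.5). The deals gave sets of similar size, with a mean of 1044 peaks, and the unequal sizes of the dark and far-red sets move both shares, so neither can be set against the deals directly. The far-red share was 21.9% with all reads kept and 49.9% with the strand column taken as deposited. Genes with a summit between 1000 bp outside either gene end and 200 bp inside it numbered 1033 in dark and 807 in far-red among 27444 protein-coding genes. Of these, 676 were found in both, where 30.4 would be shared by independent lists. The genes came from 724 dark and 563 far-red peaks, because a summit counts for every gene in reach. Neighbouring genes can thus share 1 summit, so these gene counts are not independent. The distance limits leave out summits deeper inside genes.

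**Figure D1:**
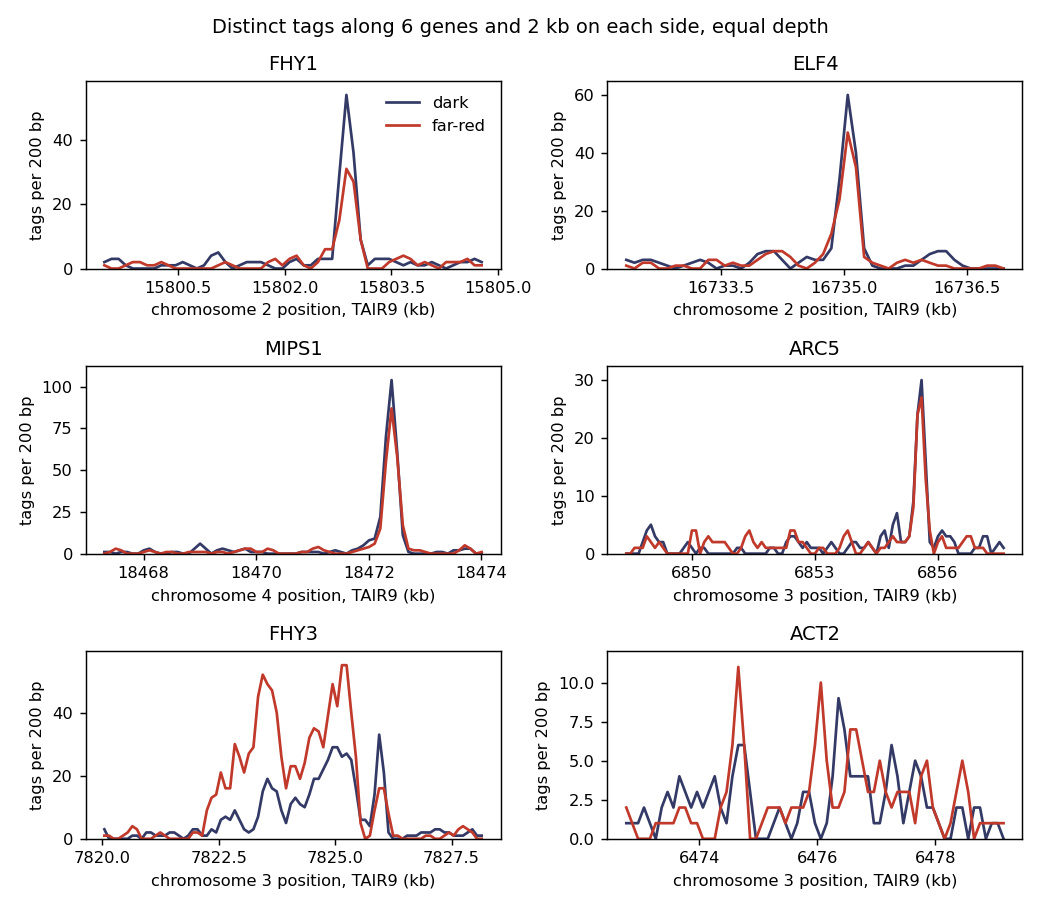
Distinct tags in 200 bp windows (vertical axes) along 6 genes and the 2 kb on each side (horizontal axes, TAIR9 position in kb), with the dark library in blue and the far-red library in red at equal depth. FHY1, ELF4, MIPS1 and ARC5 each show 1 narrow peak in both libraries, FHY3 shows tags along the gene, and the reference gene ACT2 has no called peak.

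Genes published as FHY3 targets had the highest share of bound members of the 12 lists. A peak was near 7 of the 8 in dark and 6 of the 8 in far-red, against a mean of 0.305 and 0.24 over 10000 random lists of the same size (100th percentile in each). Some of these genes were chosen in the study of these same libraries or after it, so the list is not independent evidence. FHY1, needed for the nuclear import of phytochrome A, had a peak on chromosome 2 from 15802651 to 15803100, with 65 dark and 42 far-red tags within 200 bp of the summit. The far-red over dark ratio was 0.646 (0.428 to 0.967) at equal depth and 0.884 (0.585 to 1.32) after scaling to the peaks that both libraries shared. Its homolog FHL had a smaller peak on chromosome 5 from 437101 to 437450, with 31 dark and 15 far-red tags (ratio 0.484, 0.243 to 0.924). COP1, an E3 ubiquitin ligase gene of light signalling, had a peak on chromosome 2 from 13977601 to 13978050 with 54 and 46 tags. The clock gene ELF4 (chromosome 2, 16734801 to 16735250) had 70 and 59 tags, and MIPS1 (chromosome 4, 18472151 to 18472650), a gene for myo-inositol phosphate synthase, had 133 and 114. ARC5, a dynamin-like gene of chloroplast division (chromosome 3, 6855351 to 6855800), had 40 and 37 tags. The intervals of the ratio included 1 at COP1, ELF4, MIPS1 and ARC5. ABI5, a transcription factor gene of abscisic acid signalling (chromosome 2, 15207501 to 15207800), was called in dark alone, with 20 dark and 11 far-red tags and a ratio of 0.55 whose interval reached from 0.238 to above 1, so a difference was not detectable at this depth. HEMB1 was the 1 published target without a peak in either library.

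Light signalling as a list of 26 genes had 4 members near a peak in dark (99.1th percentile of random lists) and 3 in far-red (97.7th percentile). COP1, FHY1 and FHL were bound in both and are also on the published list, so these percentiles share its limit, and PIF5, a bHLH factor gene, was called in dark alone with 18 dark and 12 far-red tags (ratio interval 0.293 to 1.46). Among 20 clock and photoperiod genes, a peak was near 2 in dark (90.0th percentile) and 3 in far-red (98.95th percentile). CCA1, a morning MYB gene (chromosome 2, 19245051 to 19245600), had the most dark tags of the bound list members, with 149 dark and 103 far-red tags (ratio 0.691, 0.532 to 0.895, and 0.946, 0.729 to 1.22, after scaling to the shared peaks). CHE, a TCP factor gene, had a peak called in both libraries with 39 and 27 tags, and counted in far-red alone because its dark summit fell outside the distance limits. MIPS1 and MIPS2 were the 2 bound genes of the 11 in the list of inositol and oxidative stress genes in each library (96.6th percentile in dark and 97.9th in far-red). MIPS1, ELF4 among the clock genes and ARC5 among the chloroplast division genes are on the published list, so the percentiles of these lists share its limit as well. MIPS2 had 32 and 23 tags.

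HEMC, the porphobilinogen deaminase gene (chromosome 5, 2665651 to 2666150), was the 1 bound gene of 28 in chlorophyll and haem biosynthesis in each library, with 63 and 49 tags. That count lay at the 52.9th percentile in dark and the 61.9th in far-red. Among 13 chloroplast division genes, 2 were bound in dark (ARC5 and ARC3, 95.2th percentile) and ARC5 alone in far-red (81.1th percentile). Of 13 light-harvesting genes, 0 had a summit within the distance limits in dark (30.5th percentile) and LHCB3 had one in far-red (81.5th percentile). Within the distance limits the hormone lists did not stand out. Auxin genes near a peak numbered 2 of 20 in dark (AFB2 and ARF19, 89.4th percentile) and 0 in far-red (27.5th percentile), and AFB2 had 13 dark and 9 far-red tags. Abscisic acid genes numbered 1 of 15 in dark (ABI5, 72.4th percentile) and 0 in far-red (31.7th percentile), and gibberellin genes 0 of 15 in each library (28.3th and 32.1th percentiles). Of the control lists, 1 of 13 reference genes (GAPC1, 47 and 34 tags) was bound in each library (75.5th percentile in dark and 80.9th in far-red). None of the 9 seed storage genes was bound in either library (35.4th and 38.1th percentiles). With summits anywhere in a gene or within 1000 bp of it, counted after seeing the data, light-harvesting genes with a peak numbered 1 in dark and 3 in far-red and light signalling genes 5 in each. Inositol and oxidative stress genes then numbered 3 and 4, clock genes 3 and 3, gibberellin genes 3 and 2, abscisic acid genes 3 and 1 and reference genes 2 and 2. The counts of the other lists were as before. No random lists were drawn for these wider counts, so whether the hormone lists stand out by them was not tested. Deeper peaks in hormone genes, named after their values were seen, were called in both libraries at RGL1 (55 dark and 44 far-red tags), RGL2 (54 and 34) and PYR1 (38 and 24). Those at RGA (18 and 10) and PYL1 (25 and 10) were called in dark alone.

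Peaks gathered just outside genes. Within 1000 bp outside a protein-coding gene lay 34.1% of dark summits (31.4 to 36.8) and 35.3% of far-red summits (32.2 to 38.5). For random tags of the same libraries the shares were 21.1% (20.4 to 21.9) and 19.2% (18.6 to 19.9). Inside genes lay 51.2% of dark summits (48.3 to 54.0) and 49.6% of far-red summits (46.3 to 52.9), against 59.9% and 61.6% of random tags. Pericentromeric bins held 128 of the dark peaks and 120 of the far-red peaks.

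The direct comparison of light conditions used the 1391 peaks found in either library. At equal depth 281 peaks had at least 2-fold more tags in dark and 78 at least 2-fold more in far-red, with the interval of the ratio clear of 1, and 1032 passed neither way. This is a rule of size, not a test of the conditions. Summits lay inside a protein-coding gene for 60.85% (54.88 to 66.6) of the 281 and 64.1% (52.44 to 74.66) of the 78. For the 1032 the share was 48.93% (45.84 to 52.03). In the 20 random deals of the pooled tags, between 13 and 38 peaks passed in 1 direction. The split turned with the scaling: when the median ratio of the 727 shared peaks, 0.731, was set to 1, 89 peaks passed toward dark and 159 toward far-red. Library and sequencing lane are the same split, so the lane and the light condition cannot be told apart.

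**Figure D2:**
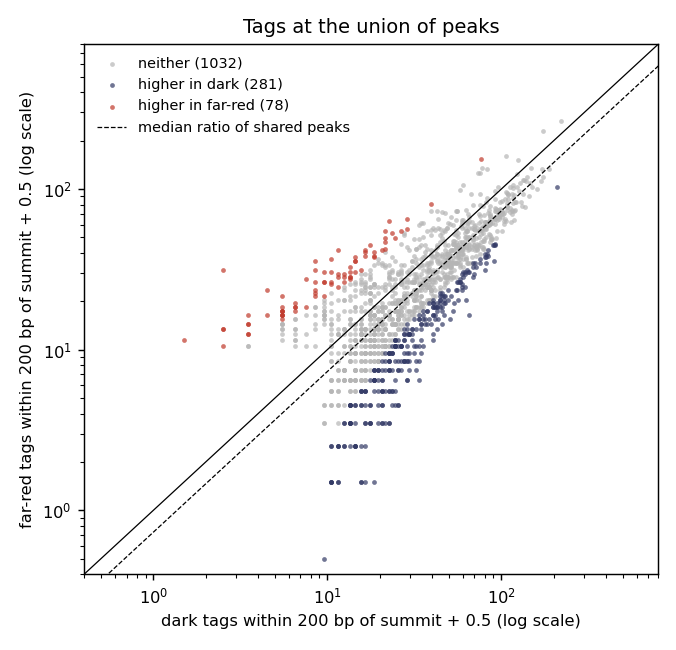
Distinct tags within 200 bp of each of the 1391 summits in dark (horizontal axis) and far-red (vertical axis), both with 0.5 added and on log scales, each point being 1 peak. The solid line marks equal tags and the dashed line the median ratio of shared peaks, 0.731, and 281 peaks pass the 2-fold rule toward dark and 78 toward far-red.

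Of the list members near a peak, FHL, ARC3 and ARF19 passed the rule toward dark, as did a peak deeper inside PYL1, an abscisic acid receptor gene, with 25 and 10 tags. ARC3, a chloroplast division gene, had 24 dark and 5 far-red tags (chromosome 1, 28163851 to 28164550, ratio of dark over far-red 4.8, 1.79 to 16.1), with its right tags lying left of its left tags (spacing -71.5 bp), unlike the order at most peaks. The most enriched window within the distance limits of ARC3 had 6.855-fold enrichment in dark and 8.036-fold in far-red, where no peak was called. ARF19, an auxin response factor gene, had 35 and 10 tags (3.5, 1.70 to 7.92), with 57 bp between left and right tags. Among peaks within the distance limits of a gene, the largest dark over far-red ratios were at AT1G30320 (9 dark and 0 far-red tags, lower bound of the ratio 1.97), at ASL15, a LOB-domain gene (16 and 1 tags, ratio 16, 2.49 to 671), at AT2G04170 (11 and 1 tags, spacing -52 bp), at AT5G57580 (11 and 1 tags) and at SAPX, the stromal ascorbate peroxidase gene (10 and 1 tags). These peaks, ARC3 and ARF19 also passed after scaling to the shared peaks. FHL, PYL1 and RIF10 passed the rule toward dark at equal depth (RIF10 with 34 and 14 tags, ratio 2.43, 1.27 to 4.90) and did not pass after that scaling. All 17 of the most enriched genes had a far-red over dark ratio under 1, from 0.412 to 0.920, and RIF10 was the 1 among them that passed the rule. With the scaling to shared peaks their ratios ran from 0.564 to 1.26 and none of the 17 passed.

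The list members with peaks that passed toward far-red were LHCB3, LHCB1.3, HFR1, FAR1 and the reference gene UBQ10. LHCB3, a light-harvesting gene, had 12 dark and 28 far-red tags (chromosome 5, 22039101 to 22039650, ratio 2.33, 1.15 to 5.04), with 34 bp between its left and right tags. A second LHCB3 entry, inside the gene, was called in dark with 18 and 25 tags (22039151 to 22039350, ratio 1.39, 0.728 to 2.70). It lay within the far-red interval and was listed apart because the summits were more than 200 bp apart. Overlapping intervals were thus called in both libraries, so the site is not particular to either. The other 4 had peaks deeper inside the gene than the distance limits allow, and LHCB1.3, HFR1, UBQ10 and PYL1 are named here after their values were seen. LHCB1.3, a light-harvesting gene, had 8 dark and 31 far-red tags (chromosome 1, 10478601 to 10478950, ratio 3.88, 1.74 to 9.76) with a spacing of 183.5 bp. HFR1, a bHLH factor gene of far-red signalling, had 8 and 26 tags (chromosome 1, 465851 to 466150, ratio 3.25, 1.43 to 8.31) with a spacing of 219 bp. UBQ10, a ubiquitin gene, had 39 and 80 tags (ratio 2.05, 1.38 to 3.09) with a spacing of 103 bp. A second UBQ10 entry, called in dark within the far-red interval, had 57 and 98 tags (ratio 1.72, 1.23 to 2.43). Its spacing was 10.5 bp and it did not pass. Among peaks within the distance limits of a gene, the largest ratios were at ATPD, the delta subunit of the chloroplast ATP synthase (2 and 13 tags, ratio 6.5, 1.47 to 59.3), AT5G18490 (2 and 13 tags), MBD9, a methyl-CpG-binding domain gene (3 and 16 tags, 5.33, 1.53 to 28.6), MEE49 (3 and 14 tags) and AT1G74675 (8 and 35 tags, 4.38, 1.99 to 10.9). Each of these 5 passed under both scalings, and the spacing of left and right tags was 28 bp at AT5G18490. Of the 78 peaks, 24 lay in pericentromeric bins (30.8%, 20.8 to 42.2), against 9 of the 281 dark peaks (3.20%, 1.47 to 5.99) and 12.7% of all 1391 peaks. The spacing between left and right tags had a median of 86.5 bp for the 78 and 182 bp for the 281. It reached 100 bp in 33 of the 78 (42.3%, 31.2 to 54.0) and in 263 of the 281 (93.6%, 90.1 to 96.2). Without the FHY3 locus and a part of chromosome 2 known from general knowledge to carry mitochondrial DNA, left out after seeing the data, 59 peaks were higher in far-red and 281 in dark. Of these 59, 5 lay in pericentromeric bins (8.47%, 2.81 to 18.7), against 9.2% of all peaks outside these regions, and the spacing reached 100 bp in 31, with a median of 106 bp.

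Tags along the FHY3 gene itself were spread over most of its length. Within the gene 260 dark and 539 far-red tags were counted at equal depth (ratio 2.07, 1.78 to 2.41), and the 2 kb on each side held 24 and 20. A called dark peak on chromosome 3 from 7825851 to 7826050 had 35 dark and 25 far-red tags (ratio 0.714, 0.410 to 1.23). FAR1, the closest homolog of FHY3, had a peak inside the gene in far-red alone (chromosome 4, 8616451 to 8616800), with 2 dark and 31 far-red tags (ratio 15.5, 3.94 to 134) and 39 bp between left and right tags.

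Light-harvesting genes carried more far-red than dark tags along the gene, a measurement added after seeing the data. For 12 of the 13 members the far-red count was higher, and the median log2 of far-red over dark was 0.69, at the 100th percentile of 10000 lists matched on tags, whose median was 0.07. LHCB1.3 had 28 dark and 66 far-red tags, LHCA4 41 and 77, LHCB3 34 and 60, and LHCB1.2 was the exception with 18 and 14. Medians were 0.38 for light signalling genes (99.5th percentile), 0.49 for inositol and oxidative stress genes (98.2th percentile), 0.35 for reference genes (95.2th percentile), 0.29 for clock genes (94.8th percentile) and -0.22 for gibberellin genes (7.33th percentile). Seed storage genes had a median of 0.36 (83.4th percentile), on 55 dark and 63 far-red tags in all. By count of members, far-red was higher for 11 of the 13 reference genes, 7 of the 8 published targets and 6 of the 15 gibberellin genes. Pooled over members, the far-red over dark ratio was 1.655 (1.433 to 1.913) for light-harvesting genes and 1.402 (1.238 to 1.588) for reference genes. These 2 intervals overlapped. Scaling to the shared peaks shifted the median of all genes to 0.45, and with it that of gibberellin genes to 0.23, while scaling to bins without a peak left it at -0.27.

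**Figure D3:**
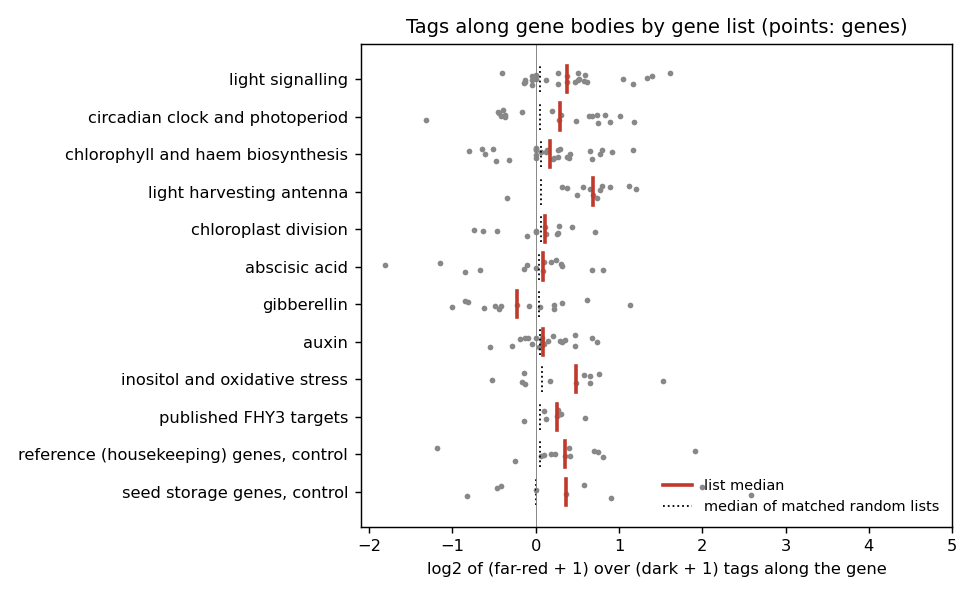
Log2 of far-red over dark tags along the gene, with 1 added to each count (horizontal axis), for the genes of the 12 lists (vertical axis), each point being 1 gene, solid bars the list medians and dotted bars the medians of random lists matched on tags. The light-harvesting median is 0.69, and the matched lists have a median of 0.07.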

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

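All tests in this part were chosen after the results were seen, except the scaling to the shared peaks, which was chosen beforehand. Organelle DNA made up a large share of the reads and was outside the peak analysis. Chloroplast reads were 43.4% of the dark library and 48.7% of the far-red library, and mitochondrial reads were 1.67% and 2.72%, with no control library to set beside them.

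Light-harvesting genes carried more far-red than dark tags along the gene, with a median log2 ratio of 0.69 against 0.07 for lists matched on tags. Leaving out the LHCB1 and LHCB2 copies left a median of 0.67 over 8 genes, above the range that held 95% of matched lists, which ended at 0.44, which argues against reads shared between near-identical copies. A candidate explanation is that tags were gathered over the bodies of transcribed genes: reference genes lay at the 90.2th percentile of length-matched lists in tags per kb in dark and at the 99.8th in far-red, which leaves it open. Seed storage genes, the other control list, lay at the 11.45th percentile in dark and the 43.25th in far-red. Light-harvesting genes lay at the 100th in each library, but this was not particular to them. Light signalling genes also lay at the 100th in each, auxin genes at the 100th and 99.99th, and chlorophyll and haem genes at the 99.91th and 99.86th. Abscisic acid genes lay lower, at the 84.2th and 76.06th. The sequencing lane stays open too, since 0 lanes held reads of both libraries. Greater FHY3 binding along these genes in far-red light was not tested separately from these.

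More peaks were higher in dark than in far-red, with 281 against at most 38 in 1 direction in the random deals, which argues against counting noise. A library-wide difference in enrichment stays open: the median ratio over the 727 shared peaks was 0.731 (resampling interval 0.714 to 0.75), which largely restates the excess. Tags at the 1391 union peaks were 8.24% of dark and 6.29% of far-red tags, which restates it as well. The maximum of strand spacing rests on no peak call. At full depth it was 3.155-fold the level at the same distance on the left in dark and 2.164-fold in far-red. After scaling to the shared peaks 89 passed toward dark and 159 toward far-red, so the excess toward dark did not remain. Whether such a difference accounts for these peaks too stays open, since the spread between libraries of 1 condition was not measured. Whether any library-wide part came from the precipitation or from less FHY3 on chromatin in far-red light was not tested.

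The FHY3 gene was covered by tags over most of its length. At least 3-fold of the genome mean was reached in 85.7% of its 21 windows of 200 bp in dark and in 90.5% in far-red, while the 20 windows beside it had 0 and 2, which argues against binding at one site as the whole cause. The far-red over dark ratio along the gene was 2.07 (1.78 to 2.41). DNA of the transgene, or tags gathered over a strongly transcribed gene, may still account for the coverage, and neither was tested separately.

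Part of chromosome 2, from 3.2 to 3.6 Mb, known from general knowledge to carry an insertion of mitochondrial DNA whose edges were not checked here, held 53 peaks, of which 19 were higher in far-red and 0 in dark. Its far-red over dark ratio was 1.78, against 1.90 for the mitochondrial genome at equal nuclear depth and 1.03 in each of the neighbouring stretches from 2.8 to 3.2 Mb and from 3.7 to 4.1 Mb. Those stretches leave out the dense bin from 3600001 to 3700000, directly beside the part. That bin held 3659 dark and 4546 far-red tags, with a ratio of 1.242 (1.189 to 1.298), so a smaller far-red excess reached beyond 3.6 Mb.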

How the results depend on the processing

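Of the 92 values tried under other settings for the main counts and shares, 55 stayed within 1.5 times the count or within the interval. Keeping all reads gave 33760 dark and 37248 far-red peaks, 14870 and 16282 genes, and shared shares of 21.9% of far-red and 24.2% of dark peaks, so the calls depend on removing duplicates and the order of dark and far-red turned in all 3. A genome-wide background gave 2253 and 1861 peaks, 1672 and 1380 genes, and shares of 60.2% and 49.8%. Peaks found in each of 2 random parts of a library numbered 594 and 411, with 573 and 422 genes and shares of 90.8% and 62.8%, a setting that lowers the depth by construction. With the strand column as deposited, chosen after seeing the data, there were 796 dark peaks, 671 and 529 genes, and shares of 49.9% and 39.3%. The far-red share was 84.7% at full depth (51.7% for dark), 85.5% with a 5-fold minimum, 88.1% with q under 1e-05 (64.1% for dark), 77.8% with 400 bp windows, 83.9% without pericentromeres and 75.4% with summits within 100 bp (55.8% for dark). Genes within 2000 bp of a dark peak numbered 1573. Of the peaks that differ, scaling to the shared peaks gave 89 toward dark and 159 toward far-red, all reads gave 518 toward dark, and a spacing of left and right tags of at least 100 bp, chosen after seeing the data, left 33 toward far-red. Except as stated, the cause was not tested. Of 228 values for single genes and lists, 23 moved, and none of those that passed the 2-fold rule changed sign. With a limit of 2000 bp outside a gene end, light signalling members near a peak numbered 7 in dark and 5 in far-red. Gibberellin members then numbered 2 and 1, and chlorophyll and haem members 2 in dark. No paired analysis was possible because each condition had 1 library, and for the same reason no library could be left out. The share of peaks with the FHY3 binding site, with its other distances, the motif panel and lists matched on promoter GC content were not run. Depth limits the weak peaks: in simulated dark data 46.3% of peaks planted at 10 times the genome mean were found, and 6 of 33 such peaks with a 3-fold difference passed the 2-fold rule.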

Other observations

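The comparisons in this part were chosen after the data were seen and have no test beyond counting intervals. Among 2189 gene bodies with at least 60 tags, 239 had a far-red over dark interval above 1 and 240 below 1. The genes named here were picked from these after their values were seen, and no gene group was tested. GAPA, a Calvin cycle gene, had 30 dark and 73 far-red tags (ratio 2.43, 1.57 to 3.86), CA2, a carbonic anhydrase gene, had 85 and 165 (1.94, 1.49 to 2.55) and GGT1, a peroxisomal aminotransferase gene, had 50 and 110 (2.2, 1.56 to 3.14). DIN10, known as a dark-inducible gene, had 249 and 476 tags (1.91, 1.64 to 2.24), and BXL1, a beta-xylosidase gene, had 334 and 579 (1.73, 1.51 to 1.99). CCA1 had 62 dark and 126 far-red tags along the gene (2.03, 1.49 to 2.80), while the peak beside it had a ratio of 0.691 at equal depth and 0.946 (0.729 to 1.22) after scaling to the shared peaks.

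More dark tags lay along AT4G12450 with 62 dark and 18 far-red tags (dark over far-red 3.44, 2.01 to 6.19), PLA-I{gamma}1, a lipase gene, with 102 and 36 (2.83, 1.92 to 4.27), EDL3, an F-box gene, with 58 and 20 (2.90, 1.72 to 5.09) and the invertase gene ATBFRUCT1 with 57 and 20 (2.85, 1.69 to 5.01). Along FAR1 there were 29 dark and 91 far-red tags (far-red over dark 3.14, 2.05 to 4.95).

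The bin of 100 kb with the most dark tags, on chromosome 5 from 11700001 to 11800000, held 5780 dark tags, 11.1-fold the median bin, and 7004 far-red tags, 13.3-fold. In pericentromeric bins, which held 13.7% of dark and 14.9% of far-red distinct tags, pairs of tags on the same strand were most frequent at a spacing of 178 bp in both libraries, with 52.0 partners per 1000 tags in dark against a median of 33.7 over all spacings (1.55-fold) and 52.2 against 29.8 in far-red (1.75-fold). Spacings under 60 bp were not searched. In chromosome arms the highest values were at 60 bp in dark (1.62-fold the median) and 62 bp in far-red (1.38-fold). Both lay at or next to the edge of the search, so they show no preferred spacing in the arms. No repeat annotation was used here.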
